A study of Homo sapiens with 78 samples.

How the data were processed

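The series holds 78 arrays of human cells in 42 groups. RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised to Affymetrix arrays, per the labels' protocols. The study set out to compare parental tumour cells with cultivated tumour stem-like cells and human embryonic stem cells, per the series' design text. The parental and stem-like cells came mostly from established lines. The embryonic stem cell and oocyte arrays, 3 parental HT29 arrays and 2 parental MCF7 arrays were taken from other series, per the labels. The method used to summarise and normalise the scanner signals is not given in the sources used here.

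The authors' deposited value table gives 1 score per probe set and array. The values behave as z-scores: over the 78 arrays each probe set had a mean between -0.0672 and 0.0481 and an SD between 0.807 and 1.006, with a median SD of 1.003. Single values ran from -6.54 to 8.62. A difference of 1 in a probe set therefore means 1 SD of that probe set over all arrays of the series. For a gene with several probe sets, whose mean varies less, a unit is not an SD of the gene. The scale before the scores were formed is not stated. Whether spread grew with level was examined only in the probe sets with the least spread within groups. Their SD within groups was 0.231, 0.207, 0.234 and 0.235 for values in the 4 unit-wide ranges from -2 to 2. It did not grow with the level there, and the other probe sets were not examined. Scores of this kind carry no expression level, no fold change and no detection call. A large score can belong to a gene that is dim everywhere, and a gene whose value varies strongly over the series has its differences made smaller. A difference in one gene cannot be set against that in another as an amount of RNA. The array shows no read depth, and the number of arrays limits the precision.

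Probe sets were named through the platform annotation given with the data. Of 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none, and of those with 1 symbol 40984 had a gene identifier that matched the current gene table. Probe sets of XIST and Y-linked genes (59) were left out throughout. A gene's value was the mean of its probe sets with 1 symbol, which gave 19740 genes, 10511 of them with several probe sets. BMI1 and POU5F1, which the naming rule also listed, had no probe set with a single symbol and were not analysed here. No 2 arrays were copies of each other, the highest correlation between any pair being 0.856. All 78 value columns matched a sample.

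Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment, and a gene was called changed at an adjusted p under 0.05. One fit held the in-house groups of 9 lines (A549, FaDu, SAS, HT29, SW480, MCF7, AT/RT, HTB186 and U87mg, written U87 here), with a coefficient for each group and 16 residual degrees of freedom. Groups with 1 array are assumed there to vary like the replicated groups. A consensus over the 9 lines used 1 stem-like minus parental difference per line. The embryonic comparisons used 1 value per line or group, with the 2 MCF7 Snail arrays averaged as 1 group. BT, BT12 and BT16, whose labels conflict on the tumour, were among the parental groups. A549 and FaDu entered the stem-like panel with several groups each, counted as independent, so its groups are not all separate lines. The primary glioblastoma cultures, the oxygen arrays and the oocytes had fits of their own. CBX5 over the lines and the shift along the embryonic axis were tested with exact two-sided sign-flip permutation tests, whose smallest possible p with 9 lines is 0.00391. The labels number the replicates as biological without saying what separated them, so p-values measure the spread between these arrays.

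The lists, the tests and most alternatives were fixed before the data were examined (the closing section names the alternatives added later), with 4 departures that the scores made necessary. The tests had been planned for log2 values, with a filter on dim genes, with the brightest probe set standing for a gene and with a trend of variance on level. None of these can be had from scores, so no filter and no trend were used and probe sets were averaged. Averaging and the lack of a filter had been planned as alternatives.

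The 25 gene lists cover stem cell programmes, chromatin complexes, cell cycle and stress pathways, and markers of other cell types. They were tested with camera (preset correlation between genes) over all 14 comparisons, with Benjamini-Hochberg adjustment over the 25 lists of a comparison. Of 350 tests, 107 passed with the preset correlation and 13 with a correlation estimated from the data. Of the 13, 3 were in the arrays labelled CD133+ A549, 2 in the A549 panel, 3 in HT29 spheres, 1 in SW480 Snail cells, 1 in each embryonic comparison and 2 in oocytes. Where a list is given below as passing, the adjusted p with an estimated correlation is named beside it.

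Genes are named by a rule: the 10 largest rises and the 10 largest falls among changed genes whose arrays or lines all lay on one side of the other group's mean (for the 9 lines, at least 8), with the 5 smallest p given where none passed. CBX5, CBX1, CBX3, PROM1, SNAI1, TWIST1, SOX2 and NANOG were tested in every comparison. Each is named where it passed, and in part where it did not, although the rule set before the data were examined was to name all. From each list, up to 4 members with the smallest p were named. The share of line-specific expression kept, over the 100 genes highest in a parental line against the other lines, and the correlations between groups across genes were chosen after the data were seen. Genes are not independent replicates in such correlations. For groups of 1 array, the 5 largest rises and falls are values with no test. The standing of a list on such an array is its median's percentile among 10000 random lists of the same size. These were not matched on mean expression, which z-scores do not carry, or on correlation between members. Such a percentile is therefore not a p-value. The genes of the single AT/RT sphere array are not listed, because the labels do not say that these cells are an established line.

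The limma fits were tested on simulated gene values, with 100 genes changed by 1 unit and 100 by 2 in each comparison of 19740 genes. The noise had the fitted spread of each gene and was independent between genes. The sign-flip and camera tests were tried on separate simulated values. Averaging of probe sets and scaling of arrays were not simulated. The added checks without arrays in doubt or without single lines were also run for the gene lists and the named genes. Alternatives tried were quantile normalisation, centring of each array, other choices of probe set, a filter on noisy genes, other sets of arrays, the replicate number or the line as a block, the line as replicate, and leaving out each array or line. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.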

Results

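Expression was measured on 78 arrays of human tumour cells, embryonic stem cells and oocytes, as z-scores per gene over the series. Tumour stem-like cells had been obtained in 4 ways: sorting for the surface protein CD133, growth as floating spheres, selection for radio-resistance, and over-expression of Snail, Twist or Bmi1. The lung adenocarcinoma line A549 had 3 parental arrays, 3 arrays labelled CD133+, 1 radio-resistant array and 1 Snail array. The head and neck lines were FaDu (2 parental, 1 Bmi1, 1 Twist) and SAS (3 parental, 6 sphere). The colon lines were HT29 (2 parental, 2 sphere) and SW480 (2 parental, 2 Snail), and the breast line MCF7 had 1 parental array and 2 different Snail arrays. U87mg glioma cells (U87 below), HTB186 cells and AT/RT (atypical teratoid/rhabdoid tumour) cells had 1 parental and 1 sphere array each. The HTB186 arrays are titled AT/RT as well, and were kept here as a line of their own. The parental groups BT, BT12 and BT16, of 1 array each, are titled AT/RT and named glioblastoma in the source label, and entered the parental panel alone. Differences below are stem-like minus parental in units of the z-scores, as the mean of a gene's probe sets, followed by ± the standard error.

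The genes named in the labels were examined first. PROM1, which encodes CD133, stood at -0.91 ± 0.04 (SD, n = 3) in the arrays labelled CD133+ and at -0.94 ± 0.03 (SD, n = 3) in parental A549, a difference of 0.03 that did not pass the test. In HT29 cells PROM1 was at 1.35 ± 0.06 (SD, n = 2). SNAI1, which encodes Snail, did not change in the SW480 arrays labelled Snail (difference 0.02) or over the Snail arrays of 3 lines (difference -0.17). It lay 0.66 above parental on both MCF7 Snail arrays, and stood at -1.11 in the A549 array labelled Snail, against 0.09 ± 1.37 (SD, n = 3) in parental A549. TWIST1 was at 0.19 in the FaDu array labelled Twist and at -0.12 ± 0.01 (SD, n = 2) in parental FaDu. A probe outside the part of a gene that was introduced would not measure it, so for the over-expressed genes these values do not check the labels.

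In the arrays labelled CD133+ A549, genes of detoxification, of inflammatory signalling and of epithelial structure lay far below parental A549, and chromatin genes lay above. These arrays kept 1.83% of the excess of 100 genes specific to parental A549. Whether the differences arose within A549 cells therefore cannot be told here. Of 19740 genes, 6073 changed, 3213 higher and 2860 lower. Of 24 oxidative stress response genes 23 fell and none rose, 24 lower adjusted over the list alone (median difference -2.43; camera adjusted p = 6.9e-24, and 7.5e-05 with an estimated correlation), among them ALDH3A1 (-3.82), NQO1 (-3.56), ABCC2 (-3.51) and AKR1B10 (-3.25). Of 24 inflammatory cytokine genes 16 fell and none rose, 17 lower adjusted over the list alone (median -1.63; adjusted p = 0.0046 with an estimated correlation). Polycomb genes went the other way, with 15 of 25 higher and 1 lower, and 15 and 2 adjusted over the list alone (median 0.80; adjusted p = 0.015 with an estimated correlation), including RBBP4 (2.25), PCGF6 (2.27), MTF2 (1.92) and PCGF3 (1.91). Of 30 heterochromatin genes 13 rose and none fell, 14 and 1 adjusted over the list alone (median 0.57; adjusted p = 0.19 with an estimated correlation), such as the remodeller SMARCA4 (2.28) and the nuclear lamina receptor LBR (1.56).

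Epithelial genes were lower in the same arrays: 16 of 30 fell and 1 rose, as many adjusted over the list alone (median -0.63; adjusted p = 0.13 with an estimated correlation), with the keratins KRT18 (-1.95) and KRT8 (-1.87) and the transcription factor ELF3 (-2.81) among them. Mesenchymal genes did not pass as a list (3 rose, 8 fell, adjusted p = 0.089), and TGFBI (-2.75), S100A4 (-2.97) and AXL (-2.32) fell. Of the tumour stem cell markers ALDH1A1 (-2.34), ABCG2 (-2.80), ABCC1 (-2.52) and CD24 (-1.89) fell; the list had 10 members lower and 5 higher (adjusted p = 0.28 with an estimated correlation). The largest rises were in CALCB (4.45 ± 0.28), CITED1 (4.43 ± 0.22), SERTM1, LINC01424, LINC00632, LINC01694, ZCCHC18, ALDH8A1, KRTAP19-1 and NKX2-3 (3.85 ± 0.57). The largest falls were in PTGR1 (-4.58 ± 0.21), FAM230C, LINC00473, CXCL3, INSL4, AKR1C4, the fibrinogen gamma chain FGG (-4.05 ± 0.18), TM4SF20, ITGB1-DT and HORMAD1 (-3.90 ± 0.19). CBX5 (-0.40), CBX1 (0.26) and CBX3 (0.62) did not pass, and TWIST1 rose by 1.01. These arrays kept 1.83% of the excess that 100 genes specific to parental A549 showed over the other lines, while the radio-resistant A549 array kept 101% and the A549 Snail array 74.9%.

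**Figure D1:**
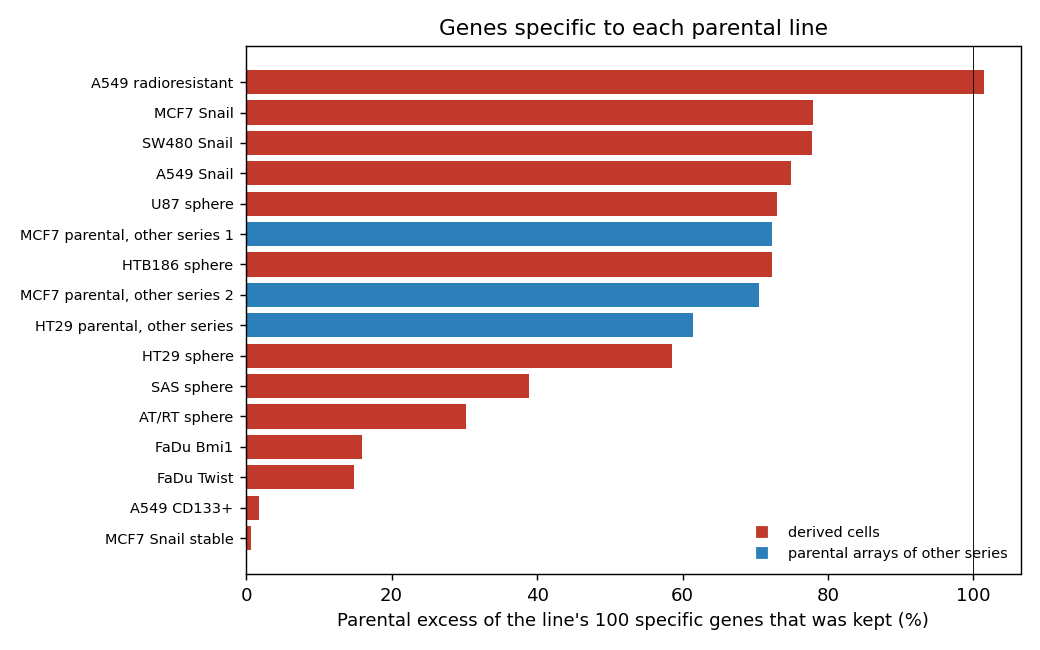
Share, in percent, of the parental excess of each line's 100 most specific genes that was kept in cells derived from it (red) and in parental arrays of the same line from other series (blue). The arrays labelled CD133+ A549 (1.83%) and the MCF7 Snail stable clone (0.60%) lie lowest, and the parental arrays of other series keep between 61.4% and 72.3%.

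The lung panel as a whole gave equal weight to the A549 arrays labelled CD133+, radio-resistant and Snail. It changed 920 genes, 443 higher and 477 lower, and the oxidative stress genes (16 of 24 fell, none rose, 19 lower adjusted over the list alone; adjusted p = 0.00017 with an estimated correlation) and the inflammatory cytokine genes (9 of 24 fell, none rose, 11 lower adjusted over the list alone; adjusted p = 0.0092 with an estimated correlation) were lower. Both list results rested on the arrays labelled CD133+: without them, where 2 single arrays are assumed to vary like the replicated groups, no gene of either list passed over all genes, and the medians were -0.05 (camera adjusted p = 0.64) and -0.17 (adjusted p = 0.22). AKR1C4 (-2.50 ± 0.21), THSD7A (-2.33 ± 0.13) and FAM230C (-3.19 ± 0.37) were among the largest falls, and LRRC4B (2.10 ± 0.49), RAB3A (1.85 ± 0.31) and the neurofilament gene NEFL (1.59 ± 0.31) among the largest rises. TWIST1 rose by 0.64. LRRC4B, NEFL and TWIST1 did not pass without the arrays labelled CD133+. CBX5 differed by -0.10 and did not pass. The gene count without the arrays labelled CD133+ was 35. It was 552 without parental A549 replicate 2 and 1665 after quantile normalisation.

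The radio-resistant and Snail A549 arrays have no replicates, and their values carry no test. On the radio-resistant array 1 of 34 cell cycle genes lay above parental A549 (median difference -1.24), and 3 of 28 DNA repair genes did (median -0.94). None of 10000 random lists of either size had a median as low. Members of such lists can vary together, which random genes do not reproduce, so this is no test. The largest single values there were NF1 (6.76), HS3ST6 (5.39) and KLB (4.98), and PUS7 (-3.59), SETD1B (-3.57) and KIRREL3 (-3.36), and SNAI1 differed by 2.63. On the A549 Snail array 19 of 25 p53 target genes lay above parental A549 (median 0.55). FGG (-3.93), CES1 (-3.78), LOC101927247, SPINK6 and FGB (-3.43) were lowest there, and BAAT (5.19), SLCO1B1 (4.04), LOC101927636, PDE11A and IFNE highest.

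In spheres of SAS, an oral cancer line, interferon and inflammatory genes rose, and single genes of mitosis and replication fell. Of 34 interferon response genes 17 rose and none fell, as many adjusted over the list alone (median difference 0.79, and 1.11 after centring the arrays), including RIGI (1.73), IFIT2 (1.91), IFIT1 (1.53) and HLA-B (1.04). The list passed with the preset correlation (adjusted p = 1.9e-09) and had an adjusted p = 0.68 with an estimated correlation. Of 24 inflammatory cytokine genes 12 rose and 1 fell, as many adjusted over the list alone, with CCL20 (1.87), TNFAIP3 (1.81) and CXCL8 (1.10) higher (adjusted p = 0.25 with an estimated correlation). The stem cell factor KLF4 rose by 2.71, the tight junction gene OCLN by 1.91 and the surface marker CD44 by 0.65. PLK1 (-2.62), MCM5 (-2.14) and MCM2 (-1.90), which act in mitosis and DNA replication, fell among 34 cell cycle genes of which 15 fell and 3 rose (adjusted p = 0.22 with the preset correlation), and so did the histone methyltransferase EHMT2 (-2.11) and the corepressor TRIM28 (-1.90).

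Among the heterochromatin protein 1 genes, CBX3 (1.13) and CBX1 (0.88) rose in SAS spheres, and CBX5 (-0.44) did not pass. The largest rises were in CIRSR (3.13 ± 0.51), CREBRF, WAKMAR2, the innate immune kinase TBK1 (2.99 ± 0.30), RPS24, RSRC2, MITD1, HSD11B1, LOC100289230 and PPP1R15B (2.77 ± 0.24), and the largest falls in TIGD5 (-3.72 ± 0.46), SLC37A2, NRM, H3C7, PSKH1, MBLAC1, ALG1, ANKRD16, ZNF213 and B9D1 (-3.16 ± 0.36). SAS spheres kept 38.87% of the excess of 100 SAS-specific genes and correlated at 0.316 with parental SAS across genes. In all, 9037 genes changed, 2767 higher and 6270 lower, and the median over all genes was -0.36. That median was -0.042 after centring each array, where 7322 genes changed, 3967 higher and 3355 lower. After quantile normalisation 6007 genes changed, 57.6% of them higher, against 30.6% as deposited. The control probe sets for Alu repeats were at 0.45 ± 0.61 (SD, n = 6) in spheres and at -1.52 ± 0.52 (SD, n = 3) in parental SAS. They ran from -0.24 to 0.08 in sphere replicates 1 to 3 and from 0.62 to 1.33 in replicates 4 to 6. The SD over all probe sets was 0.80 to 0.82 and 0.92 to 0.94 in these sets. Whether the sets were prepared apart is not known here, and all 6 arrays were tested as like replicates.

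In HT29 colon cancer spheres, cell cycle and DNA repair genes fell, and genes of hypoxia, glycolysis and cholesterol synthesis rose. Of 34 cell cycle genes 27 fell and none rose, 30 lower adjusted over the list alone (median -1.76; camera adjusted p = 1.6e-19, and 0.087 with an estimated correlation), with MCM2 (-2.49), BUB1B (-2.39) and TPX2 (-2.36). Of 31 hypoxia and glycolysis genes 20 rose and none fell, 24 and 1 adjusted over the list alone (median 1.17; adjusted p = 6.5e-05 with an estimated correlation), with the glucose transporter SLC2A1 (2.84), adrenomedullin ADM (2.70) and the glycolytic enzyme ALDOC (2.24). Of 20 cholesterol synthesis genes 11 rose and none fell, 12 higher adjusted over the list alone (adjusted p = 0.076 with an estimated correlation), with SQLE (2.34), HMGCS1 (2.30) and INSIG1 (2.29). Of 24 oxidative stress genes 10 rose and none fell, 13 higher adjusted over the list alone (adjusted p = 0.010 with an estimated correlation), with OSGIN1 (3.68), AKR1C1 (3.02) and GCLC (2.98). Of 28 DNA repair genes 16 fell and 1 rose, 18 and 1 adjusted over the list alone (adjusted p = 0.076 with an estimated correlation), led by RAD54B (-3.30).

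Chromatin and differentiation genes changed in HT29 spheres too. Of 30 heterochromatin genes 12 fell and 1 rose, 16 and 1 adjusted over the list alone (median -0.71; adjusted p = 0.021 with an estimated correlation), including UHRF1 (-2.24), DNMT1 (-1.99) and CBX1 (-1.44), while CBX5 was at -1.29 with an adjusted p of 0.062, or 0.045 after centring. The intestinal stem cell marker LGR5 fell by 3.30 and PROM1 fell by 0.68, and the intestinal differentiation genes CEACAM7 (5.26), CDH17 (3.50) and TFF3 (2.21) rose. Genes of the cornified envelope, SPRR1A (5.15), SPRR1B (5.13) and SPRR3 (4.30), rose with them, as did CDKN1A (1.99) and SNAI1 (2.02, with an adjusted p of 0.11 after quantile normalisation). The intestinal list (9 of 27 rose, 2 fell, 12 and 3 adjusted over the list alone) and the squamous list (8 of 23 rose, 1 fell, 9 and 1 adjusted over the list alone) each had an adjusted p = 0.076 with an estimated correlation. Other large rises were in NWD2 (6.00 ± 0.34), HSPA6 (5.95 ± 0.36), C3orf85, LY6G6C, DHRS9, PRB4 and PRB1, and the largest falls were in GABRP (-5.31 ± 0.27), ACKR4, NAALADL2, HEPACAM2, RNF157-AS1, NR0B2, CNGA1, AQP5, TXK and TOB1-AS1 (-3.84 ± 0.65). Against the parental HT29 arrays of another series, ACKR4 (-0.80), NAALADL2 (-0.25), HEPACAM2 (-1.22) and CNGA1 (-0.12) did not pass. CBX5 (-1.97) and CBX1 (-2.045) passed there. That comparison called 6873 genes, and laboratory and sphere culture cannot be told apart in it. Against the in-house parental arrays 2180 genes changed in total, 885 higher and 1295 lower. Leaving out 1 of the 4 arrays gave 1122 (parental 1), 1111 (parental 2), 859 (sphere 1) or 1056 (sphere 2). The Alu controls were at -0.47 ± 0.06 (SD, n = 2) in spheres and at -1.56 ± 0.02 (SD, n = 2) in parental HT29.

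Averaged over the 5 lines grown as spheres (SAS, HT29, AT/RT, HTB186 and U87), cell cycle genes fell and cholesterol synthesis genes rose. Of 34 cell cycle genes 31 fell and none rose, 32 lower adjusted over the list alone (median -1.19; camera adjusted p = 1.5e-22, and 0.18 with an estimated correlation), led by PLK1 (-2.07 ± 0.24), KIF20A (-2.05 ± 0.23) and TPX2 (-1.91 ± 0.25), and all 5 lines were lower for each of these 3 genes. POC1A, CDCA3, MYBL2, HJURP, KIF2C, KIF4A and FOXM1 (-1.89 ± 0.30) completed the largest falls. Of 20 cholesterol synthesis genes 11 rose and 1 fell, 12 and 1 adjusted over the list alone (median 0.75; adjusted p = 0.11 with an estimated correlation), with the enzymes MSMO1 (2.00 ± 0.28) and HMGCS1 (1.72 ± 0.23) and the sterol-regulated gene INSIG1 (1.59 ± 0.23) among the 10 largest rises of all genes, each higher in 5 of 5 lines. The cholesterol list median was below 0 in SAS as deposited (-0.14, and 0.18 after centring). It ran from 0.45 to 1.36 as deposited in the other sphere lines. The other large rises were YPEL4, C5AR1 (1.71 ± 0.13), TTYH1, SEC31B, RPL36A, SHC4 and MST1. Of these, YPEL4 did not pass without U87 and RPL36A not without AT/RT.

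Of 30 heterochromatin genes 9 fell and none rose over the 5 sphere lines, 10 lower adjusted over the list alone (adjusted p = 0.18 with an estimated correlation, and 0.12 without HT29 or 0.054 without U87 with the preset one), including the histone methyltransferase SUV39H1 (-1.65) and UHRF1 (-1.34), and EZH2 fell by 0.84 (not passing without U87). SOX2 was higher by 0.56 in 3 of 5 lines and rested on AT/RT, with a value of 0.15 and no call without that line. KLF4 was higher by 0.90 in 4 of 5 lines and rested on SAS (2.71), with 0.45 and no call without it, while NANOG (-0.01), PROM1 (-0.08) and CBX5 (-0.43) did not pass. In total 2821 genes changed, 1088 higher and 1733 lower. After quantile normalisation 1667 changed, and the share of higher genes was 50.9%, against 38.6% as deposited and 54.8% after centring. The Alu controls were higher in spheres than in parental cells in 5 of 5 lines, by 0.25 (HTB186) to 1.97 (SAS), and these results were not adjusted for them. AT/RT spheres kept 30.22% of the parental excess and SAS spheres 38.87%, less than parental arrays of other series kept in HT29 and MCF7. The count was 1665 without SAS. With the line as the replicate limma called 0 genes, and 1619 had an unadjusted p under 0.05.

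**Figure D2:**
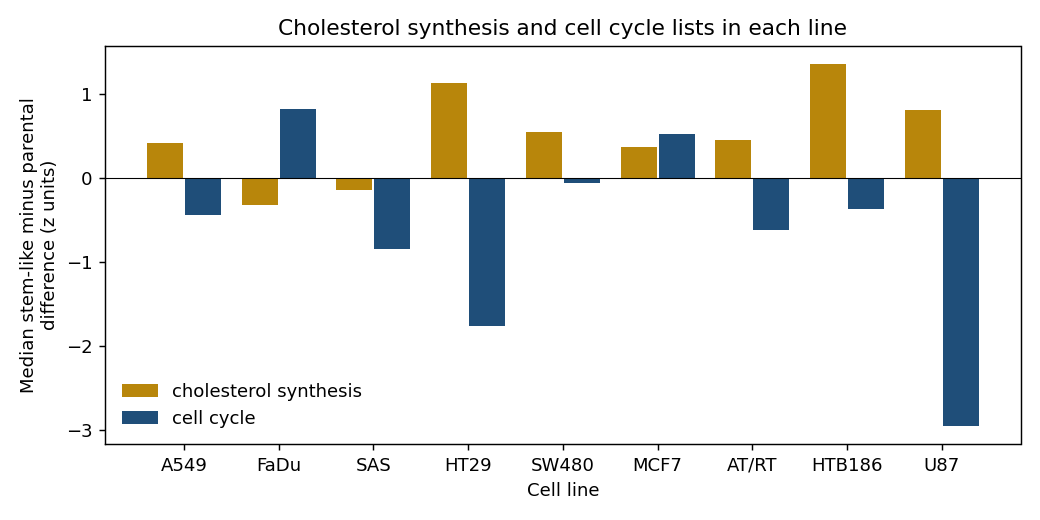
Median stem-like minus parental difference, in z-score units, of the 20 cholesterol synthesis genes (gold) and the 34 cell cycle genes (blue) in each of 9 lines. Cholesterol medians are above 0 in 7 of 9 lines and cell cycle medians below 0 in 7 of 9.

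The U87 and HTB186 sphere arrays have no replicates. In U87 spheres none of the 34 cell cycle genes lay above the parental array (median -2.96), 18 of 20 cholesterol synthesis genes did (median 0.81), and 3 of 31 hypoxia genes did (median -0.86). The mitotic genes HJURP (-5.09), KIF18B (-5.08) and KIF20A (-4.79) were among the lowest, with SPRR2B and ZNF80, and COL10A1 (7.43) and CD72 (6.25) were the highest. In HTB186 spheres 19 of 20 cholesterol genes lay above the parental array (median 1.36) and 2 of 24 inflammatory genes did (median -0.86). LINC01102 (7.35), LINC03095 (7.34), PPEF1, SLC17A6 and DNAI3 were highest there, and SMR3B (-5.57), LINC01215, SELE, CT69 and CTD-2194D22.4 lowest.

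In SW480 colon cancer cells labelled Snail, histone genes rose: 5 of 12 rose and none fell, 7 higher adjusted over the list alone (median 1.30, camera adjusted p = 5.6e-10, and 0.032 with an estimated correlation), including H2AC6 (1.86), H2BC9 (1.68), H4C8 (1.63) and H2BC12 (1.29). The antigen presentation genes HLA-DRA (-2.40) and CD74 (-1.66) fell, as did the receptor kinase AXL (-1.46) and the endothelial genes ESAM (-2.33) and TIE1 (-1.55). None of 30 epithelial genes passed over all genes (median 0.20), and 1 rose adjusted over the list alone. The largest rises were in PRR9 (4.77 ± 0.26), CPB2, the Wnt antagonist DKK4 (3.66 ± 0.22), SERPINB9P1, the intestinal stem cell factor ASCL2 (3.18 ± 0.38), KANK4, BLACAT1, MAP3K2-DT, DUSP13B and H2BC11, and the largest falls in SLC26A4 (-4.85 ± 0.29), TPSB2, BMAL2-AS1, the metastasis suppressor KISS1 (-4.05 ± 0.63), ESM1, LCN10, GZMB, VSTM1, MPV17 and PAEP. In total 398 genes changed, 187 higher and 211 lower. With any 1 of the 4 arrays left out the count was 142 (parental 1), 150 (parental 2), 145 (Snail 1) or 135 (Snail 2), and a limma fit of these arrays alone called 0 genes, with 5336 at an unadjusted p under 0.05. The Alu controls were at -0.44 ± 0.47 (SD, n = 2) in the arrays labelled Snail and at 0.63 ± 0.04 (SD, n = 2) in parental SW480.

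Over the Snail arrays of A549, SW480 and MCF7, the antigen presentation gene HLA-DRA (-1.36) and the secreted protein LCN2 (-1.78 ± 0.17) fell in 3 of 3 lines, and passed without the MCF7 stable clone and without any 1 line. The mucins MUC5AC (-1.09), MUC5B (-1.03) and MUC13 (-0.67) did not pass without A549, nor MUC5B and MUC13 without the clone, nor MUC13 after centring or quantile normalisation. Of 30 epithelial genes EPCAM (-0.77, lower in 2 of 3 lines) and CLDN3 (-0.67) fell and none rose, and 11 were lower adjusted over the list alone (median -0.37; camera adjusted p = 8.8e-07, and 0.062 with an estimated correlation). This rested on the stable clone, with a median of -2.003: without it no epithelial gene passed and the median was -0.02 (camera adjusted p = 0.77). The list's median was 0.20 in SW480 and 0.02 on the other MCF7 Snail array. On the A549 Snail array it was -0.23, with 6 of 30 genes above parental A549. No mesenchymal gene passed: CDH2 was at 0.78 and passed after centring, TWIST1 was at 0.41 and ZEB1 at 0.41, and CDH2 and ZEB1 passed without SW480. Rises were led by PRR9 (1.72 ± 0.17), CPB2, SH3RF3, ENTREP2, NKAPP1, GGPS1, GALNT13, TAS2R5, SLC9B2 and DOCK3 and falls by LINC00343 (-2.14 ± 0.47), LINC00673, TPSB2, ZPBP, SLC26A4, SLC2A2, GPER1, ADGRF5-AS1 and MAMDC4. Of 26 genes named here that passed, 12 passed without the stable clone. HLA-DRA, LCN2, LINC00673, ENTREP2, GGPS1 and DOCK3 alone also passed without each line. PRR9 (0.19), CPB2 (0.52), TPSB2 (-0.72) and SLC26A4 (-0.19) rested on SW480, with those values and no call without it, and GPER1 (-0.17) likewise on MCF7. CBX5 was at -0.06. In total 434 genes changed, 196 higher and 238 lower, and 60.9% were higher after centring, against 45.2% as deposited. The count was 128 without the MCF7 stable clone, 206 without MCF7, 256 or 247 without parental SW480 1 or 2, 262 or 228 without SW480 Snail 1 or 2, and with the line as the replicate limma called 0, with 965 at an unadjusted p under 0.05.

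The 2 MCF7 Snail arrays did not resemble each other (correlation across genes 0.026, where genes are not independent replicates). On the stable clone 1 of 30 epithelial genes lay above the parental array (median -2.003), and the progesterone receptor PGR (-5.84), CALCR (-5.82), HSPB1 (-5.68), LINC01087 and TCEAL3 were lowest, with IL26 (8.74), PRAC1 (7.64), ZCCHC12, TMEM132E and IRS4 highest. This array kept 0.60% of the excess of 100 MCF7-specific genes. The other Snail array kept 77.97% and had 33 of 34 interferon genes above the parental array (median 1.39), with CALCR (-4.97) and the membrane oestrogen receptor GPER1 (-4.46) lowest and PLEKHS1 (5.85) highest.

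The effects of sphere culture and of Snail differed in 1170 genes (548 with the sphere effect higher, 622 lower). No line was used for both effects, so that method and line cannot be told apart here. The difference was negative for 15 of 34 cell cycle genes and positive for none, with 27 negative adjusted over the list alone (median -1.40; adjusted p = 0.26 with an estimated correlation), for example TPX2 (-1.87) and MCM5 (-1.88). It was positive for LCN2 (1.505), KLF4 (1.24) and SOX2 (0.80), and negative for PHGDH (-1.44), of serine synthesis. For SOX2, AT/RT held most of the sphere effect, and SOX2 passed in 7 of the 9 settings with a line or the MCF7 stable clone left out. EPCAM (0.80), OCLN (0.97), CDH2 (-1.35) and PSAT1 (-1.24) passed as well, but not without the MCF7 stable clone, nor did CRY2, PRPF40B or POU1F1. TPX2 and PHGDH did not pass without MCF7, TPX2 not without U87 and KLF4 not without SAS, and 12 of the 30 genes named here that passed did so in each of 9 such settings, among them MCM5, LCN2 and LINC00673. The largest differences were in LINC00673 (2.83 ± 0.32), PMP2, CRY2, CALCR, ABCA5, C2CD4A, FIBIN, PRPF40B, FGFBP2 and OGN and in LINC00895 (-2.38 ± 0.57), SMAD5-AS1, SH3RF3, SELE, LINC00955, NKAPP1, LOC101927636, SLC9B2, POU1F1 and HJURP, of which POU1F1 and HJURP did not pass after quantile normalisation. The count was 614 without the MCF7 stable clone and 769 without SW480 Snail replicate 2.

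The FaDu arrays labelled Bmi1 and Twist have no replicates. They kept 15.95% and 14.84% of the excess of 100 FaDu-specific genes, less than the parental arrays of other series kept in MCF7 and HT29. Both were compared with the same 2 parental arrays, so that their agreement is not that of independent comparisons. On both, cell cycle genes lay above parental FaDu (32 of 34 with Bmi1, median 0.86; 33 of 34 with Twist, median 0.83), as did DNA repair genes (26 and 27 of 28; medians 0.94 and 0.87). Interferon genes were lower (3 and 10 of 34 above parental; medians -0.90 and -0.56). The squamous differentiation genes TGM1 (-4.24 and -4.58) and KRT4 (-4.15 and -4.30) were among the lowest on both, with ST6GALNAC1 and LOC100506639. CREG2 (5.15), LINC01527, the matrix proteases MMP12 (4.91) and MMP13 (4.45) and KIF5B were highest with Bmi1, and ZCCHC9 (4.24), KIF5B, ARHGAP11A, MOSMO and CENPQ with Twist. CBX5 was at 0.69 and 0.67 and CBX1 at 1.69 and 1.90 above parental. The Alu controls were at -1.21 and -1.15, and at -2.28 ± 0.08 (SD, n = 2) in parental FaDu.

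The study's title names CBX5, which encodes heterochromatin protein 1 alpha. Over 9 lines CBX5 was -0.23 ± 0.73 (SD, n = 9 lines) in stem-like minus parental cells, higher in 3 of 9 lines (exact sign-flip permutation test, two-sided, p = 0.375). It was higher in HTB186 (0.81), FaDu (0.68) and MCF7 (0.08), and lower in HT29 (-1.29), U87 (-1.17), SW480 (-0.61), SAS (-0.44), A549 (-0.10) and AT/RT (-0.07). Without the arrays labelled CD133+ and the MCF7 stable clone it was -0.20 ± 0.74 (SD, n = 9 lines; exact p = 0.44), higher in 4 of 9 lines, with A549 at 0.05 and MCF7 at 0.27. Its 6 probe sets gave mean differences from -0.54 to 0.20, with exact p from 0.22 to 0.86. In the 3 panels as labelled CBX5 stood at 0.03 ± 0.43 (SD, 12 parental groups), 0.06 ± 0.73 (SD, 14 stem-like groups, the 2 unlike MCF7 Snail arrays averaged as 1) and 0.13 ± 0.37 (SD, 7 embryonic lines). With those 2 arrays apart the stem-like value was 0.07 ± 0.71 (SD, n = 15), and without BT, BT12 and BT16, whose labels conflict, the parental value was 0.08 ± 0.49 (SD, n = 9).

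**Figure D3:**
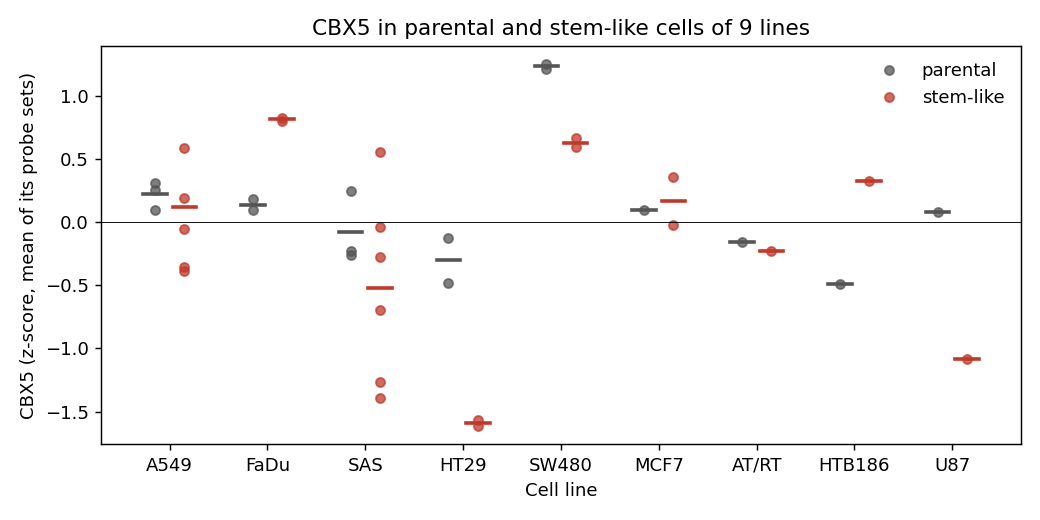
CBX5 z-score of every parental (grey) and stem-like (red) array in 9 lines, as the mean of its probe sets, with horizontal lines at the group means. Stem-like means lie above parental means in 3 of 9 lines and below in 6.

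Across the same 9 lines no gene differed between stem-like and parental cells (limma, 0 genes at an adjusted p under 0.05, 1871 at an unadjusted p under 0.05, smallest adjusted p = 0.50). In data simulated for this comparison, 59% of genes changed by 1 unit in every line and 100% of those changed by 2 were recovered. The 5 smallest p-values, none of which passed, belonged to B4GALT7 (-1.14 ± 0.20), URM1 (-0.93 ± 0.16), the sterol transfer gene STARD4 (1.09 ± 0.20), SMLR1 (-1.15 ± 0.22) and TNS3 (-0.85 ± 0.17), each on one side in 9 of 9 lines. Cholesterol synthesis (median 0.49; camera adjusted p = 3.2e-10, and 0.36 with an estimated correlation) had 6 of 20 members higher adjusted over the list alone. Cell cycle (median -0.63; adjusted p = 0.88 with an estimated correlation) and immediate early genes (median 0.26; adjusted p = 0.36 with an estimated correlation) had none. With the line as the unit, the cholesterol list median was above 0 in 7 of 9 lines (mean 0.51 ± 0.54 SD; exact p = 0.027, and 0.33 adjusted over 25 lists). Array-level fitting with the line as a block called 1942 genes.

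**Figure D4:**
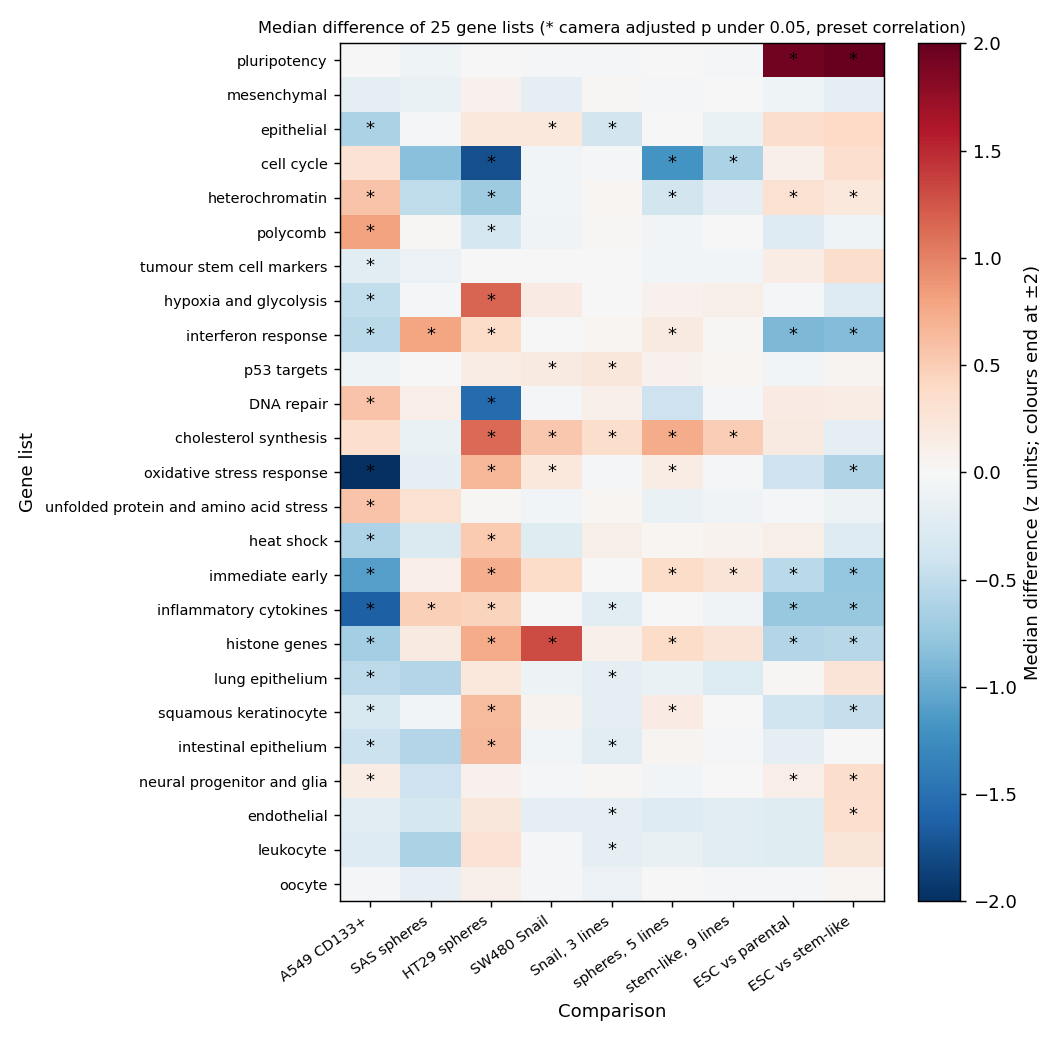
Median difference, in z-score units, of 25 gene lists (vertical) in 9 comparisons (horizontal), red for higher and blue for lower, with asterisks at a camera adjusted p under 0.05 with the preset correlation. The pluripotency list is high against parental (1.93) and stem-like (2.00) tumour cells and lies between -0.089 and 0.012 in the tumour comparisons as deposited, its sign changing with the scaling in most of them; colours end at a difference of 2.

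Embryonic stem cells, 7 lines or pools, differed from tumour cells in pluripotency genes: 23 of 24 were higher than in parental tumour cells, 24 adjusted over the list alone (median 1.93; adjusted p = 1.2e-08 with an estimated correlation) and 24 of 24 were higher than in stem-like tumour cells, again 24 over the list alone (median 2.00; adjusted p = 3.4e-08 with an estimated correlation). LIN28A (2.17 and 2.17), NANOG (2.13 and 2.20), DNMT3B (2.15 and 2.05), SOX2 (1.66 and 1.56) and PROM1 (1.68 and 1.58) were higher than in either panel. Interferon and antigen presentation genes were lower (14 and 15 of 34, against 2 and 1 higher, and 17 and 17 lower, 2 and 3 higher adjusted over the list alone; adjusted p = 0.89 and 0.61 with an estimated correlation), with TAP1 (-1.50 and -1.22) and B2M (-1.35 and -1.44). CBX1 was higher (1.34 and 1.38), and CBX5 (0.10 and 0.07) and CBX3 (0.31 and 0.00) did not pass. Against parental cells the largest rises were PIPOX, POU5F1P4, TRIM71, POU5F1B, PTPRZ1, POU5F1P3, LIN28A, MIR302B, DNMT3B and EPHX3 (2.13 to 2.20) and the largest falls DCTN3 (-2.23 ± 0.28), FAM89B, ZFYVE19, ABHD14B, IL10RB, COMMD3, PIGH, NFIC, SMIM29 and CCDC92. Values named for the pseudogenes of POU5F1 are uncertain, since such copies are near-identical to POU5F1.

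In total 2782 genes differed from parental cells (1468 higher, 1314 lower) and 3104 from stem-like cells (1808 higher, 1296 lower, or 58.3% higher against 49.2% after centring). Without BT, BT12 and BT16 the counts were 2953 and 3384. The embryonic arrays all came from other series and the tumour arrays mostly from one, so that laboratory and cell type cannot be told apart here. With each line's own parental arrays left out of the axis, stem-like cells of the 9 lines lay 5.66% ± 7.69 (SD, n = 9) of the way from the parental to the embryonic panel over all genes, above 0 in 8 of 9 lines (exact sign-flip permutation test, two-sided, p = 0.059). The share ran from -7.52% in HT29 to 20.3% in AT/RT. It was 7.30% without HT29 (exact p = 0.0078, which leaving out the only line below 0 fixes at its smallest). It was 3.83% (exact p = 0.117) without AT/RT, which had the largest share, and 3.15% (exact p = 0.32) without the arrays labelled CD133+ and the MCF7 stable clone. Over genes that differed between the panels, picked for each line without its own parental arrays, it was 5.63% (exact p = 0.012).

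Primary glioblastoma cultures were compared as radio-resistant cells (4 arrays) against spheres (3 arrays). The spheres carry a parental title and a stem-like cell type in the labels, and were counted here as stem-like. No gene passed (limma, 0 genes, 906 at an unadjusted p under 0.05, and 2 genes without sphere replicate 3), and simulated changes of 1 and 2 units were recovered for 3% and 76% of genes. Interferon response genes had a median of -1.15 in radio-resistant cells, and 19 of 34 were lower adjusted over the list alone, such as OAS3 (-1.50), ISG15 (-1.41) and HERC5 (-1.12) (camera adjusted p = 1.3e-25, and 0.54 with an estimated correlation). Cholesterol synthesis genes had a median of 0.46 (adjusted p = 0.22 with an estimated correlation). GBP5 (-3.44 ± 0.50), an interferon-induced GTPase, LINC01898, SUSD4, MC4R and GAL3ST2 had the smallest p, and none passed.

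Embryonic stem cells of the lines H1 and H9 at 4% oxygen differed from those at 20% in no gene (limma, 0 genes, 651 at an unadjusted p under 0.05). The test was weak: 1 H1 and 1 H9 array at 4% and 2 H1 and 1 H9 arrays at 20% left 2 residual degrees of freedom. Simulated changes of 1 and 2 units were recovered for 16% and 90% of genes. The hypoxia and glycolysis list had a median of 0.35 (camera adjusted p = 0.0018, and 0.96 with an estimated correlation), with P4HA1 (1.15), KDM3A (1.07) and LDHA (0.87) not passing. Oocytes (3 arrays) against embryonic stem cells carried the egg programme: 22 of 23 oocyte genes were higher and none lower, 23 higher adjusted over the list alone (median 5.00; adjusted p = 0.012 with an estimated correlation), such as the zona pellucida gene ZP2 (5.12), BMP15 (5.10) and GDF9 (5.15 ± 0.19). The glycolytic enzymes PGAM1 (-5.00 ± 0.32), GAPDH (-4.47) and LDHA (-4.09) and 17 of 24 pluripotency genes were lower (adjusted p = 0.11 with an estimated correlation for that list), and CBX5 (-1.53), CBX1 (-1.08), CBX3 (-2.73), NANOG (-2.01), PROM1 (-1.85) and SOX2 (-1.26) were lower as well. TWIST1 was higher by 1.69, not passing after quantile normalisation. In total 12044 genes differed, 7677 higher and 4367 lower, or 63.7% higher against 50.7% after centring. After quantile normalisation 7581 differed. The median over all genes was 0.37, and 0.016 after centring. The control probe sets of ACTB had a 3' minus 5' difference of -2.35 ± 0.50 (SD, n = 3) in oocytes, against values from -0.63 to 1.33 in the embryonic groups.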

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

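The tests of likeness between arrays and of the SAS arrays, and that of oxygen in spheres, were chosen after the result was seen; those of the HT29 arrays and scaling and the counts over other splits were fixed before the data were examined. The explanations by Snail and by oxygen were narrowed to the wording tested after their values had been seen, and the settings of the oxygen test were widened later still.

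The arrays labelled CD133+ A549 and the array of the MCF7 Snail stable clone resembled each other, with a correlation of 0.614 across 19740 genes, which are not independent replicates, and not parental A549 (0.0044) or parental MCF7 (0.043). The correlation was 0.616 after quantile normalisation. A correlation across genes hardly moves with a shift or scaling of whole arrays, so this value decides nothing about scaling. Snail as the whole cause is argued against only if the other 3 Snail groups carried Snail as labelled, which their SNAI1 values do not check. They kept at least 74.9% of the excess of their lines' specific genes. Cells other than the line on the label are a candidate explanation for the arrays labelled CD133+ A549 and the stable clone. These 2 groups kept at most 1.83% of that excess, where parental MCF7 arrays of other laboratories kept 70.5% and 72.3%. POU4F1 (3.43 and 3.47), HEY1 (2.99 and 3.05), IRS4 (2.73 and 4.69) and HOXD13 (2.64 and 4.47), genes picked after their values were seen, were high in both and below 0 in either parental line. A change of state shared by CD133 sorting and stable Snail expression stays open: CDKN2A, which both lines are known to lack, goes against it, at 0.80 and 0.88 in the 2 groups and -0.64 and -0.69 in parental A549 and MCF7, but it is 1 gene picked after its values were seen, and scores hold no detection call.

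In SAS spheres 69.4% of the 9037 changed genes were lower. After centring each array on its median 45.8% were lower, but centring evens this balance by construction and decides nothing. The 3 parental SAS arrays had a mean score of 0.2003 ± 0.0878 (SD, n = 3) against 0.0071 ± 0.0133 (SD, n = 6) in the spheres. A shift of the parental arrays and a fall of many genes in sphere culture cannot be told apart here, since scores hold no reference that is free of either.

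Cell cycle genes were lower and hypoxia genes higher in HT29 spheres. A fault of the in-house parental arrays as the cause of this pattern is argued against, since the cell cycle median was -2.65 and the hypoxia median 1.20 against the parental HT29 arrays of another series, though single large falls such as NAALADL2 did not pass there. Scaling of arrays is argued against by a cell cycle median of -1.67 after quantile normalisation. Low oxygen slowing division in all 5 sphere lines stays open: with a bound of 0.3 on either median 1 of 5 lines, HT29, had lower cell cycle and higher hypoxia genes as deposited, and 1 of 5 did after centring, but without a bound these counts were 2 and 4. U87, with 1 array a side, had hypoxia medians of -0.86 as deposited and -0.79 centred, and crowding or the sphere medium was not tested.

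A screen for single far values covered 42 groups of 4 to 10 values, of which chance alone would mark about 1 in 20, and marked 3. NANOG in SAS sphere replicate 1 was at -0.483, with the next array at -0.637. The epithelial list median of MCF7 was -0.9995 over 8 established lines, with the next line at -0.169. The squamous list median of HT29 was 0.627, with the next line at 0.0641. AT/RT cells were left out of this screen after a first pass that included them, because the labels do not call them an established line.

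Sphere and Snail effects differed in 1170 genes by a test of the difference itself. Outside the in-house comparisons, parental HT29 arrays from another series differed from in-house parental HT29 in 3079 genes (1545 higher, 1534 lower), with KIFC1 (3.32 ± 0.15) higher and UPK3A (-4.35 ± 0.77) and NAALADL2 (-4.17 ± 0.34) lower in the arrays of the other series. The FaDu arrays labelled Bmi1 and Twist also stood apart from their parental line, keeping 15.95% and 14.84% of its specific excess, as to a lesser degree did AT/RT spheres (30.22%) and SAS spheres (38.87%), and none of these was weighed further.

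Other splits of the arrays were counted for each comparison with at least 3 arrays or lines a side. With the real split included, 1 of 84 splits gave as many genes for SAS spheres (9037, highest other 2155). The share was 1 of 100 for the 5 sphere lines (2821, highest other 1100) and for oocytes (12044, highest other 0). It was 1 of 100 too for embryonic stem cells against parental (2782, highest other 882) and stem-like cells (3104, highest other 43). Chance sorting of the arrays is argued against for these counts, though limma called 0 genes for the sphere lines with the line as the replicate. For sphere against Snail effects (1170) the share was 2 of 100, under the 0.05 set beforehand. Another split called 1947 genes there, which leaves chance open. Chance cannot be excluded for the lung panel (920, 12 of 100, highest other 7159) or for Snail in 3 lines (434, 39 of 100, highest other 2042). Nothing can be read from the splits for the 9 lines (0; 100 of 100, highest other 0) or for the glioblastoma cultures (0; 35 of 35, highest other 1), since with no gene called any split gives as many. For the arrays labelled CD133+ the 10 splits are too few for a share under 0.05, the real value being 6073 and the highest other 4. In the lung panel and the Snail comparison, splits that called several times the real count point to a structure of the samples. The panel includes the arrays labelled CD133+ and the Snail comparison the MCF7 stable clone, which stand apart from their lines.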

How the results depend on the processing

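Centring, the smallest-spread probe set, the noisy-gene filter, leaving out arrays in doubt, leaving out embryonic lines or BT, BT12 and BT16, axis genes picked for each line and the sphere and Snail lines left out were chosen after seeing the data; the other alternatives were planned. The planned filter on dim genes and the brightest probe set cannot be formed from scores and were not run. Of the alternatives for the main results, 34 moved a count by more than 1.5 times, 3 brought a call, 1 reversed a value with no call, and 211 kept their direction and their side of the threshold or stayed within 1.5 times the count. For 341 values of named genes, 671 values after centring or quantile normalisation kept the call, with its direction where it passed, and 11 did not. SNAI1 in HT29, TWIST1 in oocytes, ZMAT3 in the lung panel, SHMT2 and SLC7A5 over the sphere lines and POU1F1 and HJURP in the sphere and Snail difference lost the call after quantile normalisation and MUC13 over the Snail lines under both, and CBX5 in HT29 and CDH2 over the Snail lines gained it after centring. Of the named genes that passed, 5 of 12 passed in the lung panel without the arrays labelled CD133+, 12 of 26 over the Snail lines and 23 of 30 in the sphere and Snail difference without the MCF7 stable clone. Without any 1 line 25 to 29 of 29 passed over the sphere lines, 16 to 19 of 26 over the Snail lines and 19 to 29 of 30 in the difference. TP53I3 turned from -1.07 to 0.0904 (no call) in the lung panel. The cause of the changes below was not tested unless stated.

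Quantile normalisation gave 1665 genes for the lung panel (920 as deposited), 6007 for SAS spheres (9037), 1667 for the 5 sphere lines (2821) and 7581 for oocytes (12044). The smallest-spread probe set gave 1400 for the lung panel. Without the arrays labelled CD133+ that panel had 35 genes, and without the MCF7 stable clone the Snail lines had 128 and the sphere and Snail difference 614. A limma fit of the SW480 arrays alone, with fewer arrays to estimate the spread, called 0 genes (5336 at an unadjusted p under 0.05). With the line as the replicate limma called 0 genes for the Snail lines (965 unadjusted) and for the sphere lines (1619 unadjusted), which then give 3 and 5 values. An array-level fit with the line as a block gave 1942 genes over the 9 lines, because spread between lines is left out there.

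Leaving out 1 array of a replicated group at a time gave 5078 to 5622 genes for CD133+ A549, 552 to 943 for the lung panel, 6072 to 8887 for SAS, 859 to 1122 for HT29, 135 to 150 for SW480, 228 to 568 for the Snail lines, 2287 to 3104 for the sphere lines, 769 to 1320 for the sphere and Snail difference, 0 to 2 for glioblastoma and 10565 to 12215 for oocytes. CD133+ A549 stands here for the arrays so labelled, and lone arrays are then assumed to vary like the other groups. Leaving out lines gave 1665 to 3421 genes for the sphere lines, 206 to 603 for the Snail lines, 599 to 1612 for their difference, 0 throughout for the 9 lines, 2174 to 2567 and 2412 to 2743 for the embryonic comparisons, 3.83% to 7.30% for the embryonic axis (exact p from 0.0078 to 0.117) and -0.365 to -0.102 for CBX5 (exact p from 0.188 to 0.688). The axis passed without HT29 (7.30%), but HT29 was the only line below 0. Leaving it out fixes the sign-flip p at the smallest that 8 lines allow, so this pass decides nothing. The axis also passed over genes that differ between the panels (9.52%, exact p = 0.0078), a choice that uses the line's own parental arrays. Picked without them the genes gave 5.63% (exact p = 0.012). It was lowest, 3.15% (exact p = 0.316), without the arrays in doubt. CBX5 turned to 0.202 (exact p = 0.508) with 1 of its 6 probe sets alone. Calls of gene lists went from 107 to 13 with an estimated correlation.

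Arrays with the same replicate number did not deviate together in A549 (correlations -0.0012, 0.0055 and -0.088) or SAS (-0.125, -0.208 and -0.119), and weakly in HT29 (0.026). In glioblastoma the values were 0.019, 0.480 and 0.224, where numbers 2 and 3 correlated best with their own number and number 1 did not. The numbers were therefore not taken as pairs. With the replicate number as a block 4021 genes were called for the arrays labelled CD133+ A549, 0 for SAS, where 6 arrays enter (limma, 6431 unadjusted), 882 for HT29 and 0 for glioblastoma (1338 unadjusted). In simulated data, changes of 1 unit were recovered for 25% of genes for the arrays labelled CD133+ A549, 10% for HT29, 11% for SW480 and 67% for the 5 sphere lines, and changes of 2 units for 81%, 71%, 70% and 99%. Signal over background cannot be read from scores.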

Other observations

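In spheres the chaperone gene DNAJB9 of the endoplasmic reticulum rose in SAS (2.63 ± 0.28), in HT29 (1.88 ± 0.40) and over the 5 sphere lines (0.93 ± 0.22), where it was higher in 3 of 5 and did not pass without SAS or without HT29. PHGDH, of serine synthesis, fell over the 5 lines (-0.77 ± 0.18, lower in 4 of 5, not passing without HT29), as did SHMT2 (-0.93 ± 0.25, lower in 4 of 5) and the amino acid transporter SLC7A5 (-0.80 ± 0.20, lower in 5 of 5), though SHMT2 and SLC7A5 did not pass after quantile normalisation or without SAS, nor SHMT2 without HT29. ATF4, the transcription factor of the amino acid response, fell in HT29 (-1.43 ± 0.35, and -0.21 with no call against the parental arrays of another series) and was at 0.02 over the 5 lines. Of the 26 genes of the unfolded protein and amino acid stress list, 1 rose and 3 fell over the 5 lines, as many adjusted over the list alone, and the list did not pass (camera adjusted p = 0.44). These genes were chosen after their values were seen.

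In the lung panel the p53 targets GADD45A (1.42 ± 0.24), EDA2R (1.565 ± 0.278) and ZMAT3 (1.04 ± 0.28, not passing after quantile normalisation) rose and TP53I3 (-1.07 ± 0.20) fell. Of 25 p53 targets 4 rose and 1 fell there, 7 and 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.075). Without the arrays labelled CD133+, GADD45A (1.28), ZMAT3 (1.39) and TP53I3 (0.09) did not pass, while EDA2R (2.265) and the list did (median 0.42; camera adjusted p = 5.4e-06, and 0.0034 with an estimated correlation). The 2 arrays left then are single ones, assumed to vary like the replicated groups, with list medians of 0.55 (Snail) and 0.18 (radio-resistant). Over the 9 lines the median of the immediate early list was above 0 in 7 (mean 0.30 ± 0.30 SD; exact p = 0.023, and 0.33 adjusted over 25 lists) and that of the endothelial list below 0 in 7 (-0.25 ± 0.27 SD; exact p = 0.039, and 0.33 adjusted), neither passing the correction. Against the parental HT29 arrays of another series, HT29 spheres had 34 of 34 cell cycle genes lower, 26 of 31 hypoxia genes higher and 1 lower, and 14 of 20 cholesterol genes higher and 1 lower. The FaDu arrays labelled Bmi1 and Twist correlated at 0.792 with each other across genes and at 0.291 and 0.289 with parental FaDu, and kept 15.95% and 14.84% of the excess of FaDu-specific genes.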
